A study of Homo sapiens with 9 samples.

How the data were processed

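The data are expression arrays of 54675 probe sets hybridised with RNA from IMR32 neuroblastoma cells, 9 arrays in 3 groups of 3. Per the labels' protocols, biotin-labelled RNA was made from 200 ng of total RNA with the Affymetrix 3' IVT Express kit. The deposited values are probe set intensities on a linear scale, and MAS5 is named in the submitters' processing notes. The software version, the scaling target and any filter are not given in the sources used here, and detection calls were not used here. The deposited values have the same 2% trimmed mean in all arrays, 250.032 to 250.035, as global scaling to 1 target gives. MAS5 subtracts mismatch-based background, which makes low signals noisy, and global scaling assumes that most transcripts do not shift together. The largest share of probe sets with identical values in 2 arrays was 0.00183%, so no array repeats another.

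Samples were grouped by their labels. The values were taken as deposited and transformed to log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. The 62 control probe sets were left out of the tests. Of the other 54613 probe sets, 41091 carried 1 gene symbol in the platform annotation, 1801 carried several and 11721 carried none. The gene identifiers of 41037 of them were found in a RefSeq gene table of assembly GRCh38, and this updated 0 symbols. Each of 19777 genes was read by its probe set of highest mean log2 signal, and genes under the 40th percentile of all probe set means (a signal of 29.2) were left out, which kept 13990. Some genes fixed for naming in advance are not discussed, because they fell under this limit or had no probe set with a single symbol.

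Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) over all 9 arrays, which share 1 estimate of the spread per gene with 6 residual and 7.35 prior degrees of freedom. P-values were adjusted by Benjamini and Hochberg's method over the 13990 genes and called at 0.05, 2-sided. The 23 gene lists were fixed before the data were examined and tested with camera at a preset correlation between genes of 0.01, with adjustment over the 23 lists, and again with a correlation estimated from the data. Lists needed 5 tested members. The test compares a list with all other genes tested, not with 0, so its direction can differ from the sign of the list's own median. No list passed at any comparison with the estimated correlation. Counts of members past the test are given over all genes and adjusted over the list alone. The lists cover neuronal, noradrenergic, mesenchymal, muscle and epithelial markers, chromatin, histone, replication, mitosis, metabolism, stress, apoptosis, interferon, retinoic acid, ERK and germline genes.

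The rule for named genes was also fixed before the data were examined. It takes CHAF1A and a few genes of neuroblastoma biology, the 6 largest rises and 6 largest falls of each induced group against uninduced among genes past the threshold with non-overlapping arrays, the 4 and 4 for day 10 against day 5, and up to 4 members of each list with the smallest adjusted p in a comparison.

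The fit and the list test were tested on simulated data before use. With 200 changed genes among 13990 in the design of day 5 against uninduced, the fit recovered 25.4% of genes changed 1.5-fold (17 of 67), 49.3% of those changed 2-fold (33 of 67) and 86.4% of those changed 4-fold (57 of 66). It called 7 unchanged genes. A list of 30 genes shifted by 0.5 was called (adjusted p = 6.83e-28) and 0 of 30 unshifted lists were. The simulated genes were drawn independently, so this does not test lists whose members move together. In the real data the estimated correlation was 0.14 in the neuronal list and reached 0.42 in cholesterol synthesis. The correlation and covariance of the comparisons against the shared uninduced arrays were set beside 100 simulations of unchanged groups.

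Alternatives fixed before the data were examined were pseudocounts of 1 and 64, no filter or a limit at the 60th percentile, quantile normalization, equal medians, eBayes without trend, array weights, only the 6 arrays compared, the mean of a gene's probe sets, every probe set on its own, the replicate number as a block, an estimated correlation, and leaving out each array. Where a call was lost without each of several arrays, the text gives the value for 1 or 2 of them. Added after the data were seen were leaving out the 2 arrays of highest actin 3'/5' ratio, that ratio as a covariate, and each other CHAF1A probe set. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.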

Results

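Transcript levels were measured in IMR32 cells, an established human neuroblastoma line that carries many copies of the transcription factor gene MYCN. The cells carried a short hairpin RNA against CHAF1A, the large subunit of the chromatin assembly factor CAF-1, which deposits histones H3 and H4 on newly copied DNA. The hairpin was expressed from a doxycycline-inducible lentiviral vector. The 9 arrays fall into 3 groups of 3 that the labels call biological replicates: uninduced cells (day 0), cells after 5 days of doxycycline at 1 µg/ml, and cells after 10 days. Each array received biotin-labelled RNA made from 200 ng of total RNA. The labels do not describe how the replicates were separated, so the p-values measure the spread between these samples, which may be partly technical. None of the 9 arrays came from cells given doxycycline without this hairpin, or from cells with a non-targeting hairpin, so every induced group differs from the uninduced group in the drug as well as in the hairpin. All uninduced arrays are of day 0, so the groups also differ in time in culture.

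The arrays were scaled alike, with a 2% trimmed mean signal between 250.032 and 250.035, and their median signals ran from 42.9 to 54.7. Signs of RNA or labelling state differed between arrays. The ratio of the 3' to the 5' control probe sets of actin was 4.17 in uninduced replicate 2, 3.62 in induced day 10 replicate 3 and 3.08 in uninduced replicate 3, and lay between 2.48 and 2.68 in the other 6 arrays. A 5' control probe set for 28S ribosomal RNA gave signals of 4757 in uninduced replicate 2 and 6024 in induced day 10 replicate 3, against 10177 to 13721 elsewhere. The 3' to 5' ratio of the GAPDH control probe sets went the other way in these 2 arrays. It was 1.20 and 1.12 there, the lowest values, against 1.27 to 1.49 elsewhere, so the actin and GAPDH controls disagree on this state. The first principal component held 27.5% of the variance. Uninduced arrays scored between -25.5 and -13.0 on it, 5 of the 6 induced arrays scored between 7.07 and 28.4, and induced day 10 replicate 3 scored -17.5, within the uninduced range. The number of arrays, 3 per group, limits the precision of every value below.

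**Figure D1:**
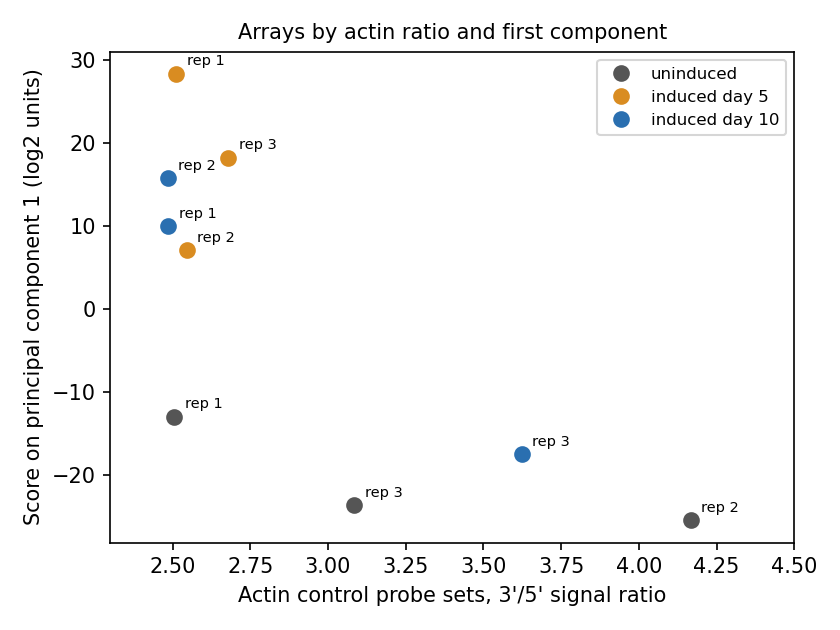
Each point is 1 of the 9 arrays, placed by its ratio of 3' to 5' actin control signal (x axis, no unit) and its score on the first principal component of log2 signal (y axis, log2 units), with colour for the group and the replicate number beside it. Uninduced replicate 2 and induced day 10 replicate 3 have the highest ratios, 4.17 and 3.62, and the second of these scores -17.5, among the uninduced arrays.

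CHAF1A itself was read by 4 probe sets, and they did not move together. The middle of them in brightness fell at day 5, from 442 ± 83.5 (SD, n = 3) in uninduced cells to 257 ± 46.7, and stood at 303 ± 8.0 at day 10. On the log2(signal + 16) scale this probe set's day 5 value was -0.75 (SE 0.16, adjusted p = 0.0405 with every probe set tested), which is 59.6% of uninduced, and its day 10 value was -0.51 (adjusted p = 0.218), or 70.3%. The dimmer of the probe sets above the brightness limit gave 259 ± 106, 111 ± 37.6 and 122 ± 17.8, with log2 fold changes of -1.07 (SE 0.29, adjusted p = 0.0913) and -0.91 (adjusted p = 0.224). The brightest probe set, of a type that can pick up related transcripts, which stands for CHAF1A in the gene-level fit by the rule set in advance, gave 578 ± 198, 590 ± 0.657 and 390 ± 181, with log2 fold changes of 0.08 (SE 0.26, adjusted p = 0.918) and -0.58 (SE 0.26, adjusted p = 0.41). The remaining probe set lay under that limit of 29.2 in the group means, at 6.03, 24.4 and 4.16. Lower CHAF1A message at day 5 therefore passed the test, adjusted over all probe sets or genes, on 1 of the 3 probe sets above the limit, and on none of them at day 10. In the order given, the 3 stood at 70.3%, 53.2% and 66.8% of uninduced at day 10 (limma, unadjusted p = 0.008, 0.00845 and 0.045). At day 5 their unadjusted p was 4.93e-04, 0.00299 and 0.768, and the brightest was not lower.

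**Figure D2:**
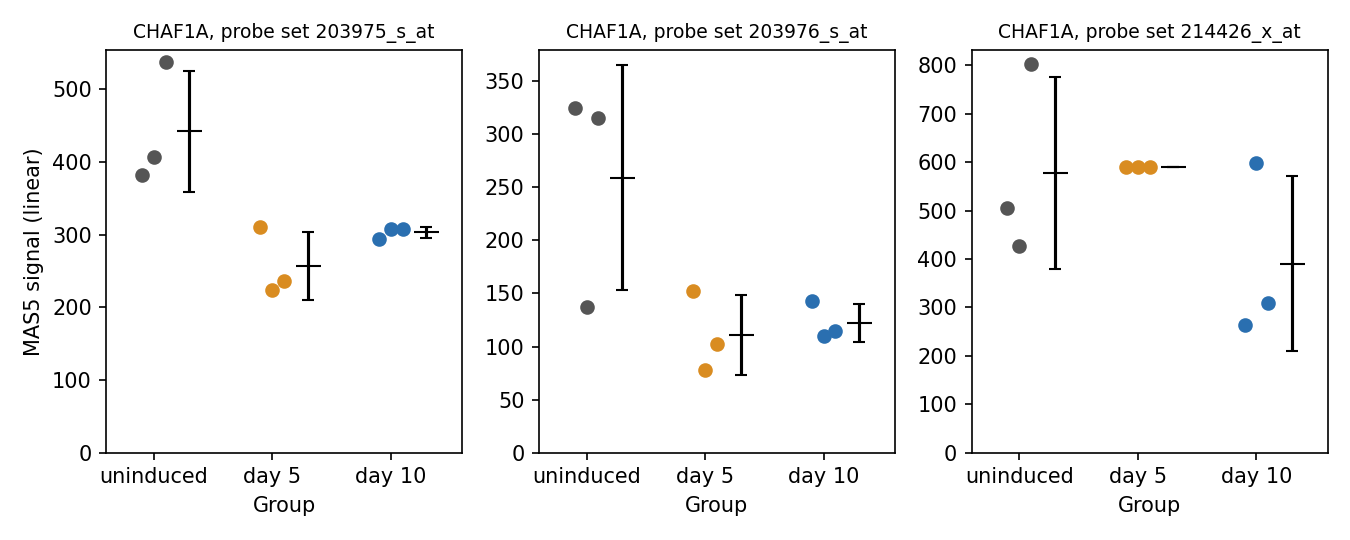
MAS5 signal on a linear scale (y axis) of the 3 CHAF1A probe sets above the brightness limit, in uninduced cells and at day 5 and day 10 (x axis). Points are single arrays and the bars beside them are the mean ± SD of 3 arrays; the middle probe set stands at 442, 257 and 303, whereas the brightest stands at 578, 590 and 390.

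The comparison of day 5 with uninduced cells asks which transcripts differ after 5 days of hairpin induction. Among the largest rises, EGR1, an immediate early transcription factor, rose by a log2 fold change of 2.95 (SE 0.60, adjusted p = 0.0236), LDB3, a protein of the muscle Z-disc, by 2.43, and LRRC55, an accessory subunit of BK potassium channels, by 2.12. FOS, another immediate early factor (adjusted p = 0.0185), UNC5A, a netrin receptor of neurons (adjusted p = 0.00512), and CD5, a lymphocyte surface glycoprotein (adjusted p = 0.0191), rose as well. Their uninduced means of 28.2, 24.5 and 23.8 lay under the brightness limit of 29.2, so the size and rank of these 3 rises were not measured. LRRC55 had uninduced signals of 25.3, 29.6 and 38.9, around that limit, so the size of its rise is imprecise. The largest falls were in YAP1, the transcriptional effector of the Hippo pathway, at -2.28 (SE 0.19, adjusted p = 1.6e-04), and PTPN14, a tyrosine phosphatase that binds YAP1, at -2.20 (SE 0.38, adjusted p = 0.0107). YAP1 signal went from 308 ± 41.8 (SD, n = 3) to 50.3 ± 3.66. HMCN1, an extracellular matrix protein, fell by 1.88, SH3BGRL fell by 1.60, AJUBA, a LIM-domain scaffold of the Hippo pathway, fell by 1.60, and HMGN5, a nucleosome-binding protein, fell by 1.59. By the rule that picked these 12 genes, all 3 arrays of one group lay beyond all 3 of the other for each. Without induced day 5 replicate 1 the log2 fold changes stayed near these values while the calls were lost, at 2.98 for EGR1 (adjusted p = 0.104), -1.77 for HMCN1 (0.172), -1.55 for SH3BGRL (0.0819) and -1.46 for HMGN5 (0.189), and with 0.102 for both FOS and CD5. PTPN14 had -2.00 (0.0524) without uninduced replicate 1. With the actin ratio as a covariate the calls of the same 7 genes were lost, with -2.20 for PTPN14 (SE 0.45, adjusted p = 0.0525), -1.65 for HMCN1 (SE 0.50, 0.161), -1.33 for SH3BGRL (SE 0.31, 0.0826), -1.32 for HMGN5 (SE 0.42, 0.176), 2.53 for EGR1 (SE 0.68, 0.124), and 0.0926 for CD5 and 0.101 for FOS. UNC5A, LDB3, LRRC55, YAP1 and AJUBA passed whichever array was left out.

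In all, 356 of 13990 genes passed an adjusted p under 0.05 in limma at day 5, 231 of them higher and 125 lower, and 99 and 30 of these changed at least 2-fold. Groups did not overlap for 22.3% of genes, where chance gives 10%. The count was 265 without the 2 arrays of highest actin ratio and 98 with that ratio as a covariate. It fell to 67 without induced day 5 replicate 1, 121, 130 and 232 without uninduced replicates 1, 2 and 3, 183 without induced day 5 replicate 3 and 235 without induced day 10 replicate 1.

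Neuronal differentiation genes rose as a group at day 5. Of 35 tested, 8 rose and none fell over all genes tested (18 rose when adjusted over the list alone), and 28 had a positive log2 fold change, with a median of 0.55 (camera, adjusted p = 4.55e-11; adjusted p = 0.338 with an estimated correlation). CHGB, a chromogranin of neurosecretory granules, rose by 1.33 (SE 0.18), ELAVL3, a neuronal RNA-binding protein, by 1.08 (SE 0.20), SYT1, the calcium sensor of synaptic vesicles, by 0.72 (SE 0.13) and MAP2, a dendritic microtubule protein, by 0.71 (SE 0.09). Genes of noradrenergic identity rose as well, with 2 of 19 past the test (5 adjusted over the list alone) and a median of 0.29 (adjusted p = 0.0143; adjusted p = 0.342 with an estimated correlation). Both were enzymes: DDC, which makes dopamine from DOPA, rose by 1.55 (SE 0.24), and GCH1, the first enzyme of tetrahydrobiopterin synthesis, rose by 1.12 (SE 0.16). MYCN, a member of that list, did not pass, at 16539 ± 2186 (SD, n = 3) in uninduced cells and 15878 ± 551 at day 5 (log2 fold change -0.05, adjusted p = 0.845). ALK, the receptor tyrosine kinase, had a log2 fold change of 0.73 (adjusted p = 0.293). The uninduced arrays held 2 of the 3 highest actin ratios, and with the ratio as a covariate the median of the neuronal list was 0.34 and that of the noradrenergic list 0.21. With the covariate ELAVL3 had 0.96 (SE 0.22, adjusted p = 0.0824). Without induced day 5 replicate 1 it had 1.04 (adjusted p = 0.0839) and SYT1 0.74 (adjusted p = 0.0643), and without induced day 5 replicate 2 the noradrenergic list kept its median (0.30) but not its call (adjusted p = 0.0546).

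The list of ERK feedback and immediate early genes rose at day 5, with 3 of 21 members past the test (9 higher and 2 lower adjusted over the list alone) and a median of 0.49 (adjusted p = 1.21e-04; adjusted p = 0.342 with an estimated correlation). Besides FOS and EGR1 the third was IER2, at 1.01 (SE 0.19, adjusted p = 0.0159). JUN had 0.97 (adjusted p = 0.0676), and SPRED1, an inhibitor of the ERK pathway, had -0.55 (adjusted p = 0.0837). FOS signal was 435 ± 117 (SD, n = 3) at day 5 against 28.2 ± 17.8 in uninduced cells, so the uninduced level lay under the brightness limit of 29.2. The FOS, EGR1 and IER2 calls were lost without induced day 5 replicate 1, with adjusted p of 0.102, 0.104 and 0.0916, although EGR1 (2.98) and IER2 (0.95) kept their size. They were also lost with the actin ratio as a covariate (adjusted p = 0.101, 0.124 and 0.0803), where EGR1 went to 2.53 (SE 0.68) and IER2 to 0.81 (SE 0.18). Without uninduced replicate 3 EGR1 went to 2.28 (adjusted p = 0.0584), and FOS did not pass (adjusted p = 0.0538). CDKN1A, the cell cycle inhibitor p21, rose by 1.03 (SE 0.21, adjusted p = 0.023), and had 1.02 (adjusted p = 0.104) without induced day 5 replicate 1 and 0.84 (SE 0.21, adjusted p = 0.104) with the covariate.

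Smaller shifts passed the list test at day 5 in 3 more lists. Genes of the unfolded protein response of the endoplasmic reticulum were mostly positive, 20 of 22, with a median of 0.17 (adjusted p = 0.0143; adjusted p = 0.48 with an estimated correlation). HERPUD1, a part of the machinery that degrades misfolded proteins, was the member that rose over all genes tested, by 0.49 (2 adjusted over the list alone). DNA replication genes had a median of 0.10 over 39 (adjusted p = 0.0189; adjusted p = 0.505 with an estimated correlation), and RRM2, a subunit of ribonucleotide reductase, rose by 0.38 (1 adjusted over the list alone). This list's median was 0.03 with the actin ratio as a covariate (adjusted p = 0.211). MYC targets and ribosome biogenesis genes fell, with 22 of 30 negative and a median of -0.13 (adjusted p = 0.0182; adjusted p = 0.35 with an estimated correlation); POLR1C and POLR1B, subunits of RNA polymerase I, fell by 0.64 and 0.47 and were the 2 members past the test, also when adjusted over the list alone. Without uninduced replicate 3 the adjusted p of these lists was 0.0835 for the unfolded protein response (median 0.15), 0.0835 for DNA replication (0.09) and 0.178 for MYC targets (-0.09). Without induced day 5 replicate 3 the median of the unfolded protein response fell to 0.09 (adjusted p = 0.0944). Without induced day 5 replicate 1 HERPUD1 had 0.54 (adjusted p = 0.0789), RRM2 0.39 (0.156), POLR1C -0.62 (0.105) and POLR1B -0.44 (0.162). With the actin ratio as a covariate these 4 calls were lost too, at 0.45 (SE 0.11, adjusted p = 0.0885), 0.40 (SE 0.10, 0.108), -0.56 (SE 0.14, 0.0926) and -0.37 (SE 0.10, 0.119).

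The other 17 lists did not pass at day 5. Mesenchymal and Schwann-type genes had a median of -0.10 (adjusted p = 0.116), with YAP1 and FN1, which encodes fibronectin and fell by 0.96 (4 of 5 other probe sets went the same way), past the test among 22 (1 higher and 3 lower adjusted over the list alone). Replication-dependent histones had a median of 0.25 (adjusted p = 0.0795), with 1 of 11 past the test, H2AC6, which rose by 0.97 and was also the 1 adjusted over the list alone. The histone list passed in 6 of 24 alternatives, among them the actin ratio as a covariate (median 0.20, adjusted p = 0.0475). In the interferon-stimulated list (median 0.01, adjusted p = 0.492) IFI27 rose from an uninduced signal of 9.82, under the limit of 29.2, and ISG15 rose by 1.12, 2 of 24 by either adjustment. Among hypoxia response genes (median 0.04, adjusted p = 0.847) STC1, a secreted glycoprotein hormone, rose by 1.45 (SE 0.16, adjusted p = 0.00112; 1 higher and 1 lower adjusted over the list alone). The retinoic acid response (median -0.04, adjusted p = 0.892) held NEDD9, a scaffold of focal adhesions, which fell by 1.14 on its brightest probe set while 0 of its 3 other probe sets went the same way, and ADD3, an actin-binding adducin, which rose by 0.47 (2 higher and 2 lower adjusted over the list alone). CDKN1A was the 1 of 25 p53 targets past the test (median -0.03, adjusted p = 0.69; 2 adjusted over the list alone). Without induced day 5 replicate 1 the calls of YAP1 and STC1 were kept. Others were lost, with -0.89 for FN1 (adjusted p = 0.152), 1.04 for H2AC6 (0.104), 0.89 for ISG15 (0.195), -0.95 for NEDD9 (0.174) and 0.51 for ADD3 (0.13), and with 0.114 for IFI27. The covariate ended the same calls, with -0.98 for FN1 (SE 0.25, 0.103), 0.87 for H2AC6 (SE 0.24, 0.135), 1.09 for ISG15 (SE 0.30, 0.135), -1.05 for NEDD9 (SE 0.30, 0.136) and 0.45 for ADD3 (SE 0.13, 0.136), and with 0.13 for IFI27.

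No member passed over all genes tested at day 5 in the remaining 11 lists. These were CAF-1 subunits and histone chaperones (median 0.02, adjusted p = 0.892), mitosis (-0.05, adjusted p = 0.573), glycolysis (0.04, adjusted p = 0.492), nuclear-encoded oxidative phosphorylation (0.01, adjusted p = 0.69) and cholesterol synthesis (-0.03, adjusted p = 0.927). They also included serine, one-carbon and polyamine metabolism (0.12, adjusted p = 0.492), the ATF4 and integrated stress response (0.10, adjusted p = 0.573) and the BCL2 family (0.04, adjusted p = 0.69). The last were germline and DUX4-target genes (0.23, adjusted p = 0.124; 0.39, adjusted p = 0.0475 with the actin ratio as a covariate), chromatin silencing factors (0.02, adjusted p = 0.692) and muscle and epithelial lineage genes (0.22, adjusted p = 0.573). Adjusted over the list alone, 1 glycolysis gene and 1 muscle or epithelial gene were higher, and 1 BCL2 family gene was higher and 1 lower. BCL2, the apoptosis inhibitor, had a log2 fold change of -0.44 (adjusted p = 0.0946). Median and test differed in sign for hypoxia (test lower), p53 targets and cholesterol synthesis (test higher) and chromatin silencing factors (test lower).

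The comparison of day 10 with uninduced cells asks the same after 10 days. DHRS2, a short-chain dehydrogenase/reductase, had the largest measured rise, at 2.67 (SE 0.19, adjusted p = 2.26e-05), from a signal of 43.9 ± 4.28 (SD, n = 3) to 366 ± 4.5. LDB3 rose by 2.61 (SE 0.28, adjusted p = 7.49e-04), LRRC55, whose uninduced signals lay around the brightness limit, by 1.94, and PPP1R17, a protein phosphatase inhibitor known from cerebellar Purkinje cells, by 1.93. UNC5A (adjusted p = 0.00813) and TMEM184A (adjusted p = 0.013) rose from uninduced means of 24.5 and 19.6, under the brightness limit of 29.2, so the size of their rise was not measured, and the 1 other probe set of TMEM184A went the other way. Among the largest falls were YAP1 at -1.91 (SE 0.19, adjusted p = 3.23e-04) and AJUBA at -1.56 (SE 0.20). PTPN14 fell from 261 to a mean of 21.6 (adjusted p = 0.00244), under the same limit, so the size of its fall was not measured either. TCF7L2, a transcription factor of the Wnt pathway, fell by 1.43 (SE 0.22), REST, a repressor of neuronal genes, fell by 1.34 (SE 0.17), and ZFP36L1, which promotes decay of AU-rich messages, fell by 1.34 (SE 0.16). REST signal was 1047 ± 169 in uninduced cells, 392 ± 72.0 at day 5 and 402 ± 65.6 at day 10. Without induced day 10 replicate 2 the adjusted p of UNC5A at day 10 was 0.058 and that of TMEM184A 0.0967, from fewer arrays.

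**Figure D3:**
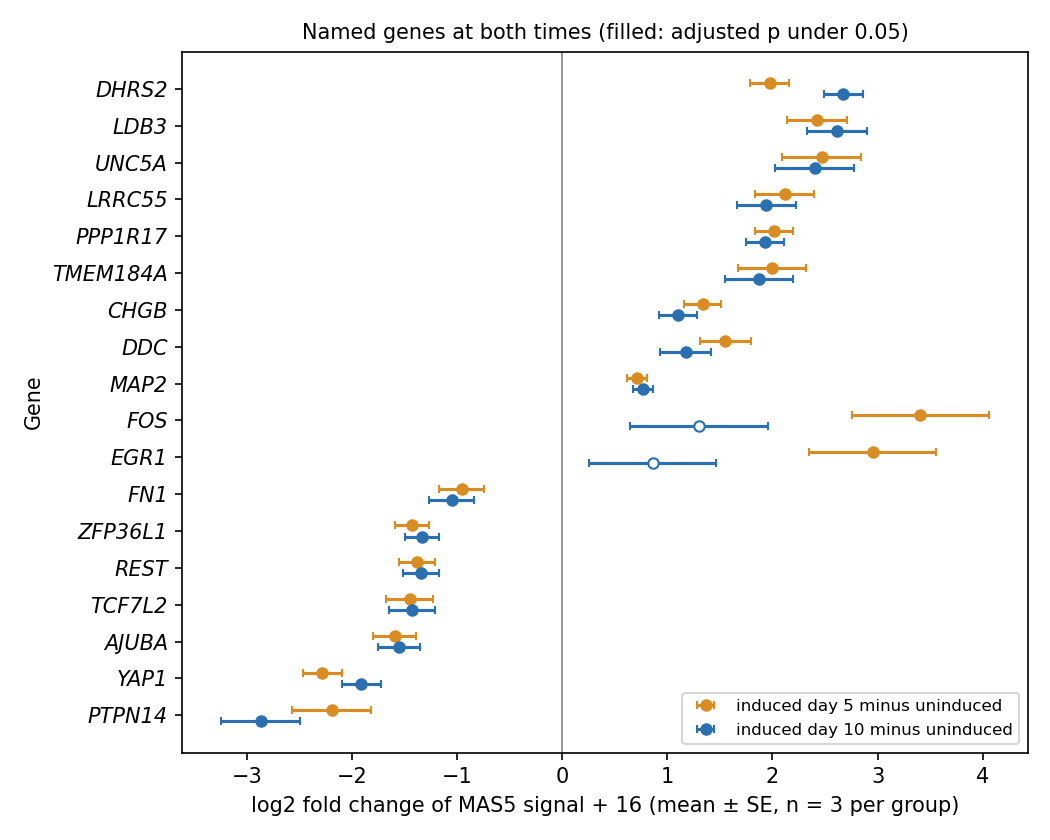
Log2 fold change of MAS5 signal + 16 (x axis, mean ± SE of the limma fit, 3 arrays per group) of 18 named genes (y axis) at day 5 and day 10, each against uninduced cells; filled points have an adjusted p under 0.05. YAP1 lies at -2.28 and -1.91, FOS and EGR1 are filled at day 5 and open at day 10, and the sizes for FOS, UNC5A and other genes with a group mean under 29.2, such as PTPN14 at day 10, are not exact.

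At day 10, 162 of 13990 genes passed, 120 higher and 42 lower, of which 61 and 15 changed at least 2-fold. Groups did not overlap for 16.5% of genes, where chance gives 10%. The count was 187 without the 2 arrays of highest actin ratio and 124 with the ratio as a covariate. It was 304 without induced day 10 replicate 3, 43 and 34 without induced day 10 replicates 1 and 2, and 51 and 93 without uninduced replicates 1 and 2.

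Neuronal differentiation genes rose as a group at day 10 too. Again 8 of 35 rose and none fell (17 rose adjusted over the list alone), 30 were positive, and the median was 0.41 (adjusted p = 1.62e-14; adjusted p = 0.0932 with an estimated correlation). STMN4, a neuronal stathmin that binds tubulin, rose by 1.58 (SE 0.23), CHGB by 1.10 (SE 0.18), the axonal adhesion molecule L1CAM by 0.95 (SE 0.16) and MAP2 by 0.77 (SE 0.09). The noradrenergic list rose with a median of 0.14 (adjusted p = 8.11e-04; adjusted p = 0.203 with an estimated correlation), and DDC (1.18) and GCH1 (0.98) were again the 2 of 19 past the test, with 3 adjusted over the list alone. MYCN had a log2 fold change of -0.04 (adjusted p = 0.933). Of the arrays behind these values, induced day 10 replicate 3 had an actin ratio of 3.62 and stood 0.26 above the uninduced mean over the neuronal list, where induced day 10 replicates 1 and 2 stood 0.52 and 0.66 above it. Without that array and uninduced replicate 2 the median of the neuronal list was 0.52 and that of the noradrenergic list 0.21, with DDC at 1.12 (SE 0.29, adjusted p = 0.105) and GCH1 at 0.94 (SE 0.21, adjusted p = 0.0633). With the covariate DDC had 1.09 (SE 0.25, adjusted p = 0.0732). Without induced day 10 replicate 2 CHGB had 0.96 (adjusted p = 0.0746), L1CAM 0.85 (0.0787), DDC 1.16 (0.151) and GCH1 0.93 (0.0779), whereas MAP2 and STMN4 passed whichever array was left out.

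Genes of mesenchymal and Schwann-type neuroblastoma cells fell as a group at day 10. YAP1 and FN1 were the 2 of 22 past the test (1 higher and 6 lower adjusted over the list alone), 17 were negative, and the median was -0.30 (adjusted p = 8.11e-04; adjusted p = 0.0932 with an estimated correlation). FN1 fell by 1.05 (SE 0.21, adjusted p = 0.0305; -0.87, adjusted p = 0.156 without induced day 10 replicate 1), and CD44, a hyaluronan receptor, had -1.05 (SE 0.24, adjusted p = 0.0558). MYC targets and ribosome biogenesis genes fell by small amounts, with 27 of 30 negative, no member past the test by either adjustment and a median of -0.18 (adjusted p = 4.65e-04; adjusted p = 0.203 with an estimated correlation). With the actin ratio as a covariate the medians of these lists were -0.31 and -0.20, and FN1 had -1.06 (SE 0.23, adjusted p = 0.0543).

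**Figure D4:**
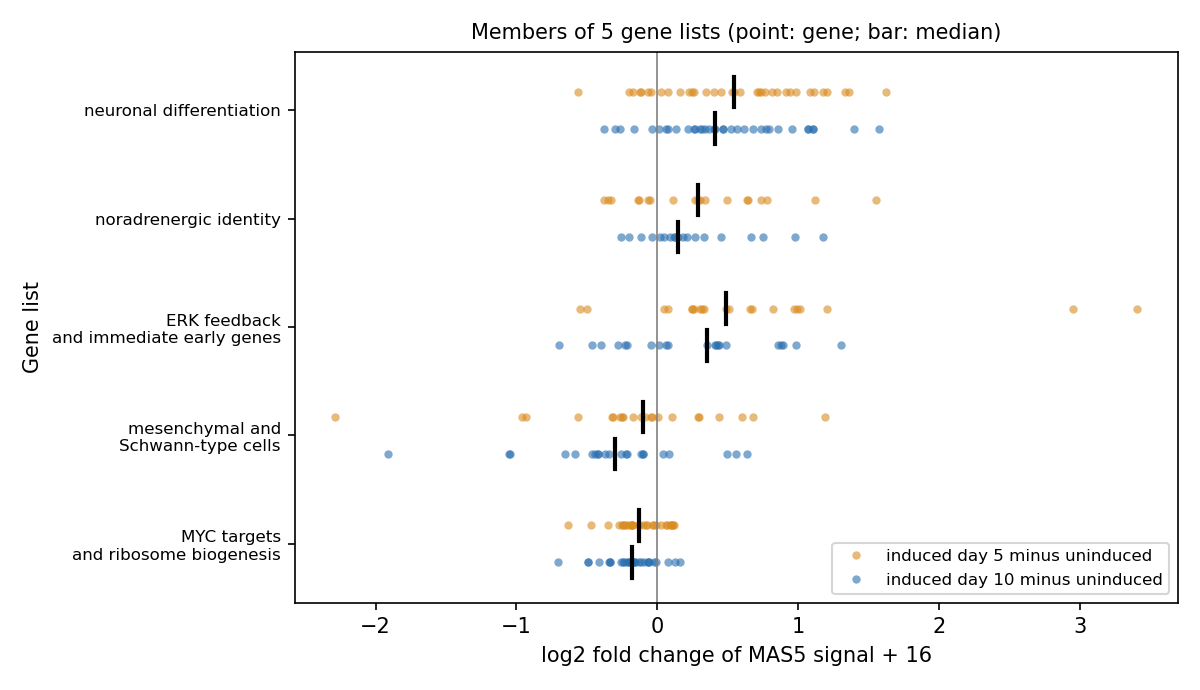
Log2 fold change of MAS5 signal + 16 (x axis) of the tested members of 5 gene lists (y axis) at day 5 and day 10, each against uninduced cells; a point is 1 gene and a black bar is the median of the list. The neuronal list has medians of 0.55 and 0.41, and the MYC target list of -0.13 and -0.18.

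At day 10, 3 more lists passed as higher than the other genes, where the median log2 fold change over all genes tested was -0.025. These were mitosis (median 0.03, adjusted p = 0.0421; adjusted p = 0.607 with an estimated correlation), glycolysis (0.06, adjusted p = 0.0457; adjusted p = 0.58 with an estimated correlation) and ERK feedback and immediate early genes (0.35, adjusted p = 0.0461; adjusted p = 0.58 with an estimated correlation). TOP2A, the topoisomerase of mitotic chromosomes, was the 1 of 38 mitosis genes past the test by either adjustment, at 0.52 (SE 0.11), and 1 of its 2 other probe sets went the same way. No member of the glycolysis or ERK list passed over all genes, and 1 and 2 were higher adjusted over the list alone. EGR1 had 0.86 (adjusted p = 0.663), and FOS, whose uninduced level lay under the brightness limit, did not pass either (adjusted p = 0.481; adjusted p = 0.0169 without the 2 arrays of highest actin ratio). Without the 2 arrays of highest actin ratio the mitosis list no longer passed (adjusted p = 0.231), although its median did not shrink (0.04). With the ratio as a covariate neither glycolysis (median 0.03, adjusted p = 0.321) nor the ERK list (0.24, 0.125) passed. Without induced day 10 replicate 1 none of the 3 passed (0.159, 0.182 and 0.159), with medians of 0.03, 0.03 and 0.18. The ERK median was also 0.18 without uninduced replicate 3 (adjusted p = 0.171). The mitosis median was 0.01 without uninduced replicate 1 (0.435) and 0.08 without induced day 10 replicate 3 (0.142). TOP2A had 0.46 (adjusted p = 0.225) without induced day 10 replicate 1, against 0.52 (SE 0.12, adjusted p = 0.0644) with the covariate. Lists called higher at day 10 numbered 5 in all. They numbered 2 with quantile normalization, with only the 6 arrays compared and with the mean of a gene's probe sets.

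The other 16 lists did not pass at day 10. In 3 of them 1 member did: STC1 rose by 0.91 in the hypoxia list (median 0.11, adjusted p = 0.183), HSP90B1, a chaperone of the endoplasmic reticulum, rose by 0.68 in the unfolded protein response (median 0.08, adjusted p = 0.0681), and RDH10, a retinol dehydrogenase, fell by 0.83 in the retinoic acid list (median 0.10, adjusted p = 0.712). Adjusted over the list alone these were 1 higher, 1 higher, and 2 higher with 2 lower. Without induced day 10 replicate 2 STC1 had 0.79 (adjusted p = 0.107), HSP90B1 0.61 (0.195) and RDH10 -0.85 (0.0746). HSP90B1 had 0.67 (SE 0.15, adjusted p = 0.0701) with the actin ratio as a covariate, and RDH10 -0.75 (SE 0.17, adjusted p = 0.0649) without the 2 arrays of highest ratio. Without the 2 arrays of highest actin ratio the hypoxia list (median 0.13, adjusted p = 0.0454) and the unfolded protein response (0.10, adjusted p = 0.0155) passed as higher, and oxidative phosphorylation passed as lower (-0.11, adjusted p = 0.0228). No member passed in CAF-1 subunits and histone chaperones (median 0.0044, adjusted p = 0.836), DNA replication (0.04, adjusted p = 0.454), replication-dependent histones (0.06, adjusted p = 0.183) or oxidative phosphorylation (-0.03, adjusted p = 0.77). The same held for cholesterol synthesis (0.03, adjusted p = 0.608), serine, one-carbon and polyamine metabolism (0.06, adjusted p = 0.587), the integrated stress response (-0.01, adjusted p = 0.889) and p53 targets (0.02, adjusted p = 0.156). It also held for the BCL2 family (-0.0037, adjusted p = 0.544), interferon-stimulated genes (0.03, adjusted p = 0.544), germline genes (0.16, adjusted p = 0.324), chromatin silencing factors (-0.05, adjusted p = 0.324) and muscle and epithelial genes (0.06, adjusted p = 0.324). Adjusted over the list alone, 1 histone gene and 2 interferon-stimulated genes were higher, 1 germline gene was higher and 1 lower, and 1 chromatin silencing factor was lower. The test pointed higher although the median was below 0 for oxidative phosphorylation, the integrated stress response and the BCL2 family, and although the mean was below 0 for histone chaperones and the retinoic acid list. It compares each list with the other genes, and the median over all genes was itself -0.025. CDKN1A had 0.60 (adjusted p = 0.233), CCND1, the G1 cyclin D1, 0.49 (adjusted p = 0.315) and ALK 0.45 (adjusted p = 0.696).

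The day 5 and day 10 calls shared 133 genes, 99 higher at both times and 34 lower at both, with none in opposite directions. UNC5A, LDB3, LRRC55, DHRS2, PPP1R17 and TMEM184A were among the shared rises, and YAP1, PTPN14, AJUBA, TCF7L2, REST and ZFP36L1 among the shared falls. Independent lists of these sizes would share 1.98 higher and 0.375 lower. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.695. In 100 simulations of unchanged groups against a shared simulated uninduced group, r was 0.50 on average (0.469 to 0.519). The covariance was 0.0764 against 0.0302 in the simulations, a difference of 0.0462. The simulated arrays, uninduced ones included, were noise drawn independently for each gene. Deviations that many genes of an array share are therefore missing from that range and would widen it. With 3 uninduced arrays the controls could not be split into parts of 2 or more. Part of the excess may therefore come from the shared controls or from such deviations. The shared count was 145 without the 2 arrays of highest actin ratio and 70 with the ratio as a covariate. It was 242 without induced day 10 replicate 3, 42 and 32 without induced day 10 replicates 1 and 2, 56 without induced day 5 replicate 1, and 45 and 70 without uninduced replicates 1 and 2.

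Day 10 was also tested against day 5 directly. No gene passed in limma, with a smallest adjusted p of 0.0724 and 762 genes at an unadjusted p under 0.05; groups did not overlap for 11.4% of genes, where chance gives 10%. FOS and EGR1, past the test at day 5 and not at day 10, had differences of -2.11 (SE 0.65) and -2.09 (SE 0.60) with an adjusted p of 0.892 each, so a difference between the times was not shown for either. DHRS2 (0.70) and YAP1 (0.37) had an adjusted p of 0.892 as well. As groups, mitosis genes were higher at day 10 than at day 5 (median 0.12, 31 of 38 positive, adjusted p = 3.67e-05; adjusted p = 0.762 with an estimated correlation). ERK feedback and immediate early genes were lower (median -0.33, 17 of 21 negative, adjusted p = 0.00437; adjusted p = 0.762 with an estimated correlation), and so were DNA replication genes (median -0.09, 31 of 39 negative, adjusted p = 0.0248; adjusted p = 0.829 with an estimated correlation). No member of these 3 lists passed by either adjustment. The neuronal list did not differ past the threshold between the times (median -0.05, adjusted p = 0.973), nor did the noradrenergic (-0.01, adjusted p = 0.973) or the mesenchymal list (-0.16, adjusted p = 0.364). The test pointed higher for the neuronal and noradrenergic lists although their medians were below 0. The median over all genes in this comparison was -0.024.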

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

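The tests of doxycycline itself, of a technical state shared by 2 arrays and of immediate early genes without FOS were chosen after the results were seen. Bounds on the mean of a gene set were first written with the standard error over its members. After the values were seen the larger of that error and the error between arrays was taken, because the members of a list move together in an array. This changed 1 reading, that of handling at harvest, and is stated there. The scores of uninduced arrays were also recomputed with each left out of its own reference, since otherwise they centre on 0 by construction.

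Other splits of the 6 arrays are too few to give a share under 0.05, since 3 against 3 makes 10 splits. At day 5 the real split called 356 genes and the highest of the others 1, so 1 of 10 splits gave as many. At day 10 the real split called 162 and the highest other 0, again 1 of 10. For day 10 against day 5 the real split called 0 and the highest other 1. There 10 of 10 gave as many, which a real count of 0 fixes in advance, so that comparison decides nothing. Every other split also mixes arrays of both groups, so a real difference between the groups widens the spread within it. The low counts of the other splits at day 5 and day 10 are therefore not those of unchanged groups.

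Neuronal differentiation genes were higher at day 10 while actin ratios differed between groups. An RNA or labelling state measured by the actin 3'/5' ratio is argued against as the whole cause: with the ratio as a covariate the mean of the list was 0.43 (error 0.08 over members, 0.16 between arrays), against 0.48 without it and 0.24 as the bound. Lower REST stays open: REST targets outside the list, chosen after REST was seen to fall, had a mean of 0.31 at day 10 (camera p = 0.0386 with an estimated correlation), but most are neuronal genes themselves and could rise with any cause of a neuronal shift, so their rise decides nothing. In induced day 10 replicate 3 alone REST was as low (448, against 432 and 327) while its targets stood only 0.06 above uninduced, against 0.38 and 0.50. Doxycycline itself rather than lower CHAF1A cannot be told apart from the hairpin, since 0 of the 9 arrays had the drug without the hairpin, and hairpin off-target effects were not tested. Time in culture cannot be told apart either, since no uninduced array is of day 5 or day 10.

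At day 5, 3 of 8 immediate early genes passed (FOS, EGR1 and IER2), and the median of the 8 was 0.99. A single outlying day 5 array is argued against as the source of the size: the lowest mean without 1 day 5 array was 1.35 against 1.42, and 1.06 against 1.13 without FOS, whose size was not measured, though the 3 calls were lost without induced day 5 replicate 1 (adjusted p = 0.102, 0.104 and 0.0916). That test left out no uninduced array. Uninduced replicate 3 was low in EGR1 (96.4, against 420 and 464) and JUN (472, against 1189 and 1101), but not in IER2 (1205, against 1236 and 882). Without it EGR1 had 2.28 (limma, adjusted p = 0.0584) against 2.95, so part of the EGR1 size rests on that array. Handling of the cultures at harvest could raise such genes within minutes and leave slower ERK targets alone. The ERK feedback and delayed targets had a mean of 0.24 at day 5, above the bound of 0.1 by more than the error of 0.12 over members, the error first written, which would count against handling. That bound was too narrow: the value rests on induced day 5 replicate 1, at 0.66, where replicates 2 and 3 stood at -0.06 and 0.11, and the error between arrays is 0.18, so handling cannot be told apart from a response to the hairpin or the drug.

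Induced day 10 replicate 3 stood apart from the other induced arrays. A mislabelled array of uninduced cells is argued against: over genes called at day 5 without day 10 arrays, on a scale from 0 (uninduced mean) to 1 (day 5 mean), it scored 0.522, where uninduced arrays left out in turn scored 0.112 to 0.211. A technical state shared with uninduced replicate 2 may contribute. The deviations of these 2 arrays from their group means correlated at 0.173 across genes, the highest of 27 pairs from different groups. The next pair, at 0.153, joined induced day 10 replicate 3 with induced day 5 replicate 2. That day 5 array had an actin ratio of 2.54 and a 28S signal of 12066, unlike the other 2. The correlation therefore does not single out a state that goes with the actin ratio. A smaller response of the culture of induced day 10 replicate 3 stays open too, as its score lay 0.375 below the lower of the other 2 day 10 arrays (0.897 and 0.995). Left-out day 5 arrays spread as widely, with 0.560, 0.798 and 1.11. The genes were chosen anew for each left-out array, so these scores do not rest on 1 gene set. They used 334, 167 and 35 genes for these day 5 arrays, 99, 113 and 197 for uninduced replicates 1, 2 and 3, and 324 for the day 10 arrays.

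Of the lists, 3 differed between day 10 and day 5, with medians of -0.0921 for DNA replication, 0.12 for mitosis and -0.33 for ERK feedback and immediate early genes. None of them passed with an estimated correlation (adjusted p = 0.829, 0.762 and 0.762). DDIT4, an inhibitor of mTORC1, had all 3 arrays lower than uninduced at day 5 (-0.32) and all 3 higher at day 10 (0.25). Its difference of 0.57 between the times had an adjusted p of 0.536 and did not pass. Probe sets without a single gene name, 6452 of which were bright enough to test, held 19 calls at day 5 (10 higher, 9 lower) and 4 at day 10 (4 higher).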

How the results depend on the processing

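Leaving out the 2 arrays of highest actin ratio, using that ratio as a covariate and reading CHAF1A from its other probe sets were chosen after the data were seen. Counts below are genes past the threshold at day 5 (356), at day 10 (162) and at both (133), in that order, and the cause was not tested except where the construction shows it. Without a filter, which tests more genes, they were 154, 84 and 66. With eBayes without trend they were 74, 38 and 30, with the mean of a gene's probe sets 175, 57 and 48, and with the actin ratio as a covariate 98, 124 and 70. Array weights gave 494, 690 and 350. Leave-one-out counts, with fewer samples, ran from 67 to 512, from 34 to 304 and from 32 to 242. For day 10 against day 5 (0), equal medians, array weights, the mean of probe sets and the replicate block each called 1 gene, and leave-one-out runs called 0 throughout. Lists called at day 5 (6) were 0 with an estimated correlation and 4 to 6 in leave-one-out runs. Lists called at day 10 (7) were 0 with an estimated correlation, 4 with quantile normalization, with only the 6 arrays compared and with the mean of probe sets, and 4 to 8 in leave-one-out runs.

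CHAF1A at day 5 (0.08) turned to -0.75 with the probe set of middle brightness, -1.07 with the dimmer one, -0.22 with the mean of all probe sets, -0.11 without the 2 arrays of highest actin ratio and -0.0791 with that ratio as a covariate, and ran from -0.11 to 0.34 in leave-one-out runs. That mean of probe sets includes the 1 under the brightness limit, which had 0.87 at day 5 and pulls the mean up. At day 10 (-0.58) the CHAF1A value ran from -0.92 to -0.33 in leave-one-out runs. The oxidative phosphorylation list at day 10 went to -0.11 (adjusted p = 0.0228) without the 2 arrays of highest actin ratio. With the replicate block the counts were 252, 111 and 101. Same-numbered arrays did not pair: their deviations correlated at -0.106 to 0.130, 1 of 9 pairs was over 0.1, and 1 of 9 arrays matched its own number best. Each named gene or list that passed was counted once per time and alternative. For named genes 1131 of these cases stayed past the threshold and 312 did not. For lists 258 cases did and 54 did not. DHRS2, YAP1, PPP1R17, LRRC55 and MAP2 passed at both times in each of 23 alternatives. Genes near the limit of 29.2 in signal, such as uninduced FOS, are measured least well.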

Other observations

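The REST targets, a set chosen after REST was seen to fall, held 50 tested genes outside the neuronal list, most of them neuronal genes too. At day 5, 38 were positive and 7 passed the test over all genes, and at day 10, 39 were positive and 6 passed, with none lower at either time (camera p = 0.056 and 0.0386 with an estimated correlation). Examples at day 10 are KIF5C, a neuronal kinesin, at 0.90 (SE 0.10), SYT11, a synaptotagmin, at 0.89 (SE 0.15), and CACNA1A, a neuronal calcium channel, at 1.21 (SE 0.22). These 3 were picked after their values were seen. With the actin ratio as a covariate the mean of the set was 0.25 at both times.

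The test of YAP targets was set out before their values were seen, but after the fall of YAP1. YAP1, PTPN14 and AJUBA, 3 genes of the Hippo pathway, fell at both times, and a hypothesis is that lower YAP1 activity would lower its targets too. The 18 tested YAP targets had a mean of 0.06 at day 5 (error 0.10 over members) and -0.0346 at day 10 (error 0.06 over members), and 0 passed the test at either time. The values decide neither way: the fall of YAP1 message was not accompanied by a shift of this set beyond its error, and members went both ways, 11 positive and 7 negative at day 5.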
